A study of Oryza sativa with 8 samples.

How the data were processed

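The measurements used were the authors' gene expression values for 8 RNA libraries from whole rice seedlings, in 4 groups of 2. The expression matrix held TPM per library as deposited by the authors, to 2 decimals, for 57403 genes, of which 55800 carry LOC_Os identifiers and 1418 are assembled MSTRG genes, and 1 line had been emptied. The authors' deposited tables of called genes gave an estimated count per gene and library, a log2 fold change, a p-value and an adjusted p-value, only for the genes the authors called. The deposited alignment and trimming tables gave each count of reads and each percent of mapped reads, GC and quality, per the file headers. The submitters' processing notes name Cufflinks 2.2.1 with no role. The aligner, the counter, the counting strand, the statistical test and the genome build were not given in the sources used here. All 5 comparisons were computed here from the deposited TPM, and the authors' p-values were used only to count shared calls.

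Genes with at least 1 TPM in at least 2 of the 8 libraries were kept, which left 25281. TPM were used as deposited, 1 was added, and log2 was taken. A limma model of 4 group means was fitted over the 8 libraries, with contrasts for treatment in each genotype, for genotype in each condition, and for the difference of the treatment effects, and with an eBayes trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, within a contrast, and an absolute log2 fold of at least 1. The 44 gene lists came from protein domains, KEGG pathways and tissue markers, covering detoxification enzymes, transporters, transcription factors, defense, hormone response, photosynthesis, growth and stress proteins. Their patterns were matched to Pfam accessions and domain names alone, and marker symbols only on the chromosome of the marker, both clarified before any test was run. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated per list, and with fry. Counts "adjusted over the list alone" repeat the Benjamini-Hochberg step within a list.

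Named genes followed a rule written before the files were opened. It took the 8 largest changes in each direction among called genes whose groups did not overlap, with a mean of at least 5 TPM in the higher group and an annotation. It added 2 called genes for each list that passed camera or had at least 4 called members, and the old yellow enzyme relatives with a mean of at least 1 TPM. For the difference of the treatment effects it took 10 in all. Symbols are those of the best rice match in Swiss-Prot and need not be the gene itself. Of all genes 6386 had such a symbol, 37151 a Pfam domain and 6538 a KEGG pathway. The identifiers of the supplied RefSeq table did not match those of the matrix, so that no coordinates were used and chromosomes were read from the locus identifiers. The matrix had 0 entries naming ScOYE3, so the level of the transgene was not analysed here.

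The limma call alone was tested on simulated data built on the ZH11 treatment comparison, with 200 of 25281 genes changed. At true log2 folds of 1, 1.5, 2 and 3 it recovered 0%, 82%, 96% and 99.5% of them, with 0, 6, 12 and 8 false calls and 0 of wrong sign. The simulated changes lay only in genes above a minimum level. Each simulated gene had the same spread in all groups and no length gradient, unlike the real libraries. These rates therefore do not measure the error of the real comparison. A fold of 1 lies at the fold threshold and gives little information on the test.

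Alternatives covered rescaling of TPM by TMM factors and by median-of-ratios factors, pseudocounts of 0.1 and 5, no filter and a stricter one, the 4 libraries of the compared groups alone, no eBayes trend, no fold threshold, a block for the replicate number, and each library left out in turn. After the data had been seen, removal of the length gradient per library with a loess curve, a term for the read-length batch, the shorter-read libraries alone, and weights by library spread were added. Software was R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, the latter only for TMM factors on TPM, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Tests on read counts were not run because estimated counts were deposited only for called genes. Annotation summary tables and sequence data were not used.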

Results

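RNA was sequenced from whole rice seedlings of the japonica cultivar ZH11 and of a transgenic line, OE1. The line is labelled as overexpressing ScOYE3, an old yellow enzyme of baker's yeast. Old yellow enzymes are flavin-dependent oxidoreductases, and 2-nitroaniline is a nitroaromatic compound. The hydroponically grown plants were 2 weeks old and were collected either untreated or 8 h after 2-nitroaniline had been added at 0.8 mM. Each of the 4 groups (ZH11 untreated, ZH11 treated, OE1 untreated and OE1 treated) had 2 libraries, each from a pool of 20 plants. The labels do not say whether the 2 pools of a group were grown or treated separately, so the p-values measure only the spread between these samples, which may be technical. Per library 42.1 M to 56.5 M trimmed reads entered alignment, and 92.1% to 93.4% of them were placed at a single position. The 10 most abundant genes took 5.84% to 7.88% of the TPM (transcript abundance scaled to a fixed total) of a library. Of the genes in the matrix, 25281 reached 1 TPM in at least 2 libraries and were tested. Fold changes are given on the log2(TPM + 1) scale, which understates the change of genes with low TPM, and each is followed by its standard error from limma with n = 2 libraries per group. Standard errors and p-values rest on 1 spread per gene, pooled over all 8 libraries.

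The replicate libraries were not equally alike. The median absolute log2 difference between replicates was 0.10 in untreated OE1, 0.17 in treated OE1, 0.20 in untreated ZH11 and 0.45 in treated ZH11, and 3272 genes differed at least 2-fold between the treated ZH11 libraries. Treated ZH11 replicate 2 stood apart along the first principal component, which held 43.9% of the variance. Its GC content was 52.04%, against 53.51% to 55.43% in the others. It also carried a gradient with gene length. Its median log2 deviation from the mean of the 8 libraries was -0.45 for genes of up to 500 nt and 0.99 for genes over 5000 nt. Treated OE1 replicate 2 had a smaller gradient of the opposite sign, reaching -0.54 for the longest genes. Mean read length after trimming was 149.1 nt in treated ZH11 replicate 2 and 149.78 nt in untreated ZH11 replicate 2, and 144.95 to 146.85 nt in the others, so that each ZH11 group held 1 library of each kind.

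**Figure D1:**
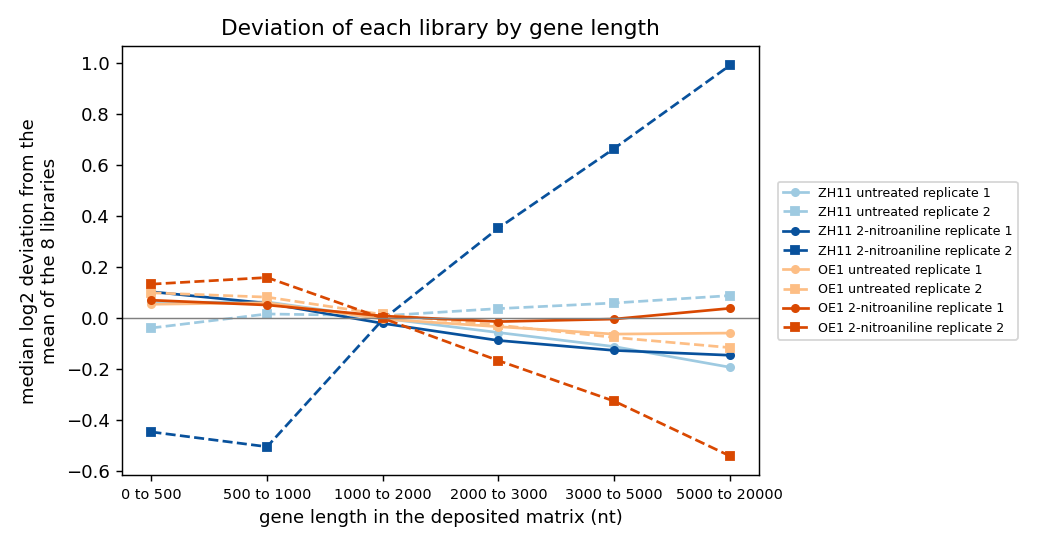
Median log2 deviation of each library from the mean of the 8 libraries (y axis) by gene length in the deposited matrix in nt (x axis), over 17423 genes with a mean of at least 5 TPM; color marks the group, circles replicate 1 and squares replicate 2. Treated ZH11 replicate 2 runs from -0.45 for the shortest genes to 0.99 for the longest, and treated OE1 replicate 2 ends at -0.54.

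The first comparison asked how ZH11 responded to 2-nitroaniline. The largest rises included genes of enzymes that modify small molecules, although no such list passed camera. The cytochrome P450 gene LOC_Os03g55240, of a family that oxidises diverse compounds, rose from 16.2 and 16.0 TPM to 174 and 226 TPM (log2 fold 3.54 ± 0.18 SE, n = 2 per group, limma adjusted p = 0.0013). The UDP-glycosyltransferase gene LOC_Os09g34250, of a family that attaches sugars to small molecules, rose by 3.43 ± 0.15 (limma adjusted p = 0.0013). A second P450 gene, LOC_Os07g23570, rose by 3.16 ± 0.16 and the BAHD acyltransferase gene LOC_Os02g28220 by 2.98 ± 0.27. The 1-Cys peroxiredoxin B gene LOC_Os07g44440, of a peroxide-reducing family, rose by 2.86 ± 0.20 from 98.8 and 122 TPM to 663 and 977 TPM. Smaller rises were seen for the UDP-glycosyltransferase gene LOC_Os01g08440 (2.76 ± 0.22), the glutathione S-transferase gene GSTU1 (LOC_Os09g20220, 2.65 ± 0.28), the P450 gene LOC_Os06g03930 (2.45 ± 0.24) and the 1-Cys peroxiredoxin A gene LOC_Os07g44430 (2.11 ± 0.24).

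Among the genes that fell, the B12D protein gene LOC_Os07g41340 dropped by 3.07 on the log2 scale (SE 0.28, limma adjusted p = 0.0128). The genes matched to the acetylserotonin O-methyltransferases ASMT2 (LOC_Os10g02880) and ASMT1 (LOC_Os09g17560), enzymes of the last step of melatonin synthesis, changed by -2.98 ± 0.22 and -2.41 ± 0.14. ASMT1 went from 43.0 and 43.6 TPM to 7.70 and 7.04 TPM (limma adjusted p = 0.00211). A probable gamma-aminobutyrate transaminase gene, LOC_Os04g52440, changed by -2.94 ± 0.31 and the anthranilate methyltransferase match LOC_Os06g13390 by -2.59 ± 0.22. The metallothionein gene MT3B (LOC_Os05g11320), of a family of metal-binding proteins, changed by -2.26 ± 0.29. The transcription factor gene WRKY76 (LOC_Os09g25060) changed by -2.08 ± 0.22, and LOC_Os01g09220, annotated as a transposon protein, by -1.75 ± 0.23. The calls of MT3B and LOC_Os01g09220 ended when TPM were rescaled by TMM factors (limma adjusted p = 0.0535 and 0.0553) or by median-of-ratios factors (0.0514 and 0.0528), and that of LOC_Os04g52440 ended with a pseudocount of 0.1 (0.0591).

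**Figure D2:**
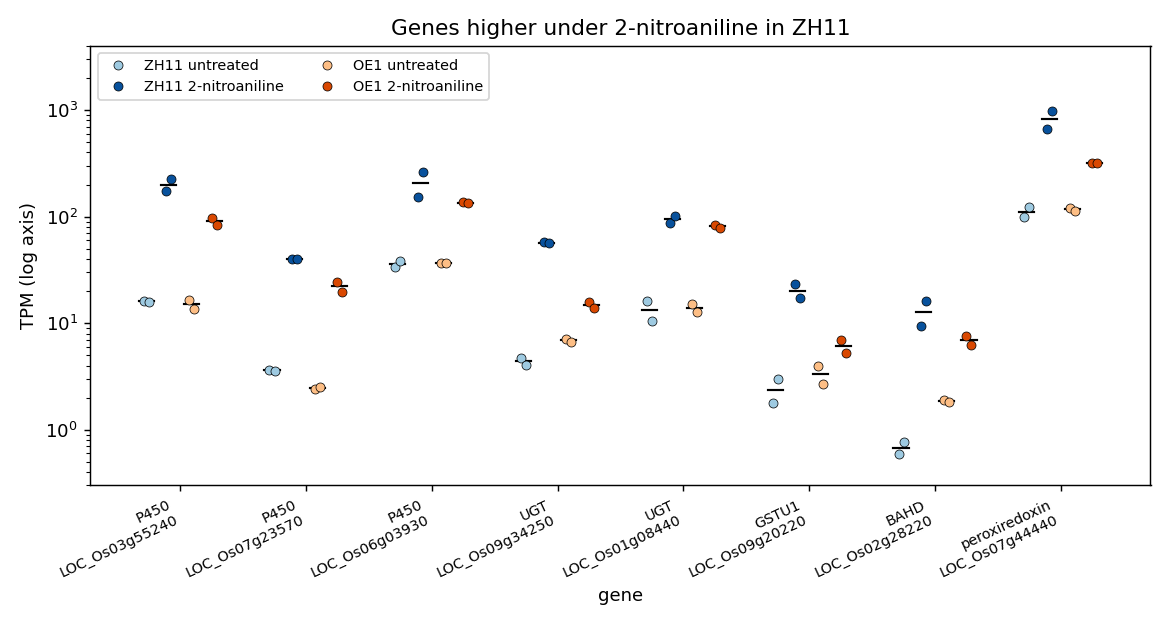
TPM of 8 genes that rose under 2-nitroaniline in ZH11 (y axis, log scale; x axis, gene), with 1 point per library, a bar at the mean of each group of 2 libraries, and color for the group. In treated ZH11 the P450 gene LOC_Os03g55240 lay at 174 and 226 TPM and in treated OE1 at 97.8 and 83.7 TPM.

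Among the lists, histones had the most members that fell. Of 56 histone genes tested, 10 fell, none rose and 46 were not called, and 16 fell when adjusted over the list alone. The histone H3 genes LOC_Os01g64640 and LOC_Os06g06460 changed by -1.72 ± 0.17 and -1.65 ± 0.17 (limma adjusted p = 0.0169 and 0.0172). Histone H3 genes are near-identical copies, so the split of reads among them is uncertain. The histone median was -0.45 (camera adjusted p = 5.58e-14, and adjusted p = 0.256 with an estimated correlation). Random lists of other genes, matched on length and mean TPM, had a median of -0.17 in the same comparison, so part of the fall goes with gene length. The median histone level, set against the mean of untreated ZH11, was -0.41 in treated ZH11 replicate 1 and -0.59 in replicate 2, the library that stands apart. The 329 genes of the cytosolic and plastid ribosome had a median of -0.31 with no member called, also when adjusted over the list alone (camera adjusted p = 1.54e-12, and adjusted p = 0.777 with an estimated correlation), and they lay at -0.15 in replicate 1 and -0.47 in replicate 2. The 26 light-harvesting genes had a median of -0.50 with no member called and 1 lower when adjusted over the list alone (camera adjusted p = 7.4e-08, and adjusted p = 0.419 with an estimated correlation). Without treated ZH11 replicate 2 their median was -0.27.

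Fewer genes of other lists were called. The 29 shoot markers, most of them light-harvesting genes, had a median of -0.47 and the 40 expansin genes, whose products loosen cell walls, a median of -0.32 (camera adjusted p = 3.78e-07 and 3.39e-05, and adjusted p = 0.414 and 0.335 with an estimated correlation). No member of either list was called and 1 of each was lower when adjusted over the list alone. The shoot markers deviated by -0.10 in treated replicate 1 and -0.41 in replicate 2 from the mean of all libraries. The 33 flavonoid pathway genes had a median of -0.36 (camera adjusted p = 0.00171, and adjusted p = 0.294 with an estimated correlation), a call that ended without treated ZH11 replicate 2 at a median of -0.33 (camera adjusted p = 0.0518). The 17 TIFY/JAZ genes, repressors of jasmonate signalling, had a median of -0.30 (camera adjusted p = 0.00616, and adjusted p = 0.335 with an estimated correlation), with no member called and 2 lower when adjusted over the list alone. Enzyme families with called members did not pass camera. Of 221 P450 genes 6 rose, 1 fell and 214 were not called, with 12 higher and 5 lower when adjusted over the list alone. Of 118 UDP-glycosyltransferase genes 4 rose and 114 were not called, with 11 higher and 3 lower when adjusted over the list alone. Of 81 glutathione S-transferase genes 3 rose and 78 were not called, with 5 higher and 1 lower when adjusted over the list alone.

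In all, 44 genes were higher and 29 lower in treated than in untreated ZH11, and 3203 genes had an unadjusted p under 0.05. These calls rest on a spread pooled over all 8 libraries, which varied less within OE1. With only the 4 ZH11 libraries limma called 0 and 0, with 551 higher and 693 lower at an unadjusted p under 0.05. With weights by library spread it called 7 and 1. With a term for read length, which separates the replicates within each ZH11 group and was added after the data were seen, the counts were 117 and 88. The counts rested on single libraries. Without untreated ZH11 replicate 1 or 2, limma called 6 and 0 higher and 5 and 0 lower genes, with 823 higher and 1268 lower at an unadjusted p under 0.05 where it called none. Without treated ZH11 replicate 1 it called 1282 and 1353, and without treated ZH11 replicate 2 it called 91 and 80. Without an untreated OE1 library the counts were 7 and 2 for either replicate, and without a treated OE1 library 6 and 2 for replicate 1 and 5 and 2 for replicate 2.

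The second comparison asked how OE1 responded to 2-nitroaniline. The enzyme genes LOC_Os07g23570 and LOC_Os03g55240 (both P450) and LOC_Os01g08440 (UDP-glycosyltransferase) rose by 2.73 ± 0.16, 2.52 ± 0.18 and 2.47 ± 0.22 on the log2 scale (n = 2 per group, limma adjusted p = 0.00371, 0.00439 and 0.0104). The jacalin-like lectin gene LOC_Os12g14440, whose best rice protein match is GOS9, rose by 3.55 ± 0.23 from 4.01 and 2.77 TPM to 45.0 and 55.1 TPM (limma adjusted p = 0.00395). LOC_Os09g07150, which has no described function, was listed at 0 in the 6 libraries of the other groups and at 16.5 and 17.4 TPM in treated OE1. The transposase match LOC_Os12g42750 rose by 3.77 ± 0.20 and was listed at 0 in all 4 ZH11 libraries. LOC_Os03g22820 rose by 2.27 ± 0.27, a call that ended with a pseudocount of 0.1 (limma adjusted p = 0.107).

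The genes that fell most in OE1 included lectin, protease and amylase genes. Jacalin-like lectin genes LOC_Os06g07250 and SALT (LOC_Os01g25280, a salt-induced protein) changed by -3.17 ± 0.25 and -2.95 ± 0.24 (limma adjusted p = 0.00688 and 0.00807). LOC_Os06g07250 has GOS9 as its best rice protein match, as does LOC_Os12g14440, which rose. The cysteine protease gene LOC_Os09g39090, a vignain precursor, changed by -3.09 ± 0.22 and LOC_Os09g39070, a thiol protease of the same kind, went from 44.1 and 42.5 TPM to 6.69 and 4.15 TPM. The alpha-amylase gene AMY1.1 (LOC_Os02g52700), whose product degrades starch, changed by -2.38 ± 0.24. The B12D gene LOC_Os07g41340 went from 22.5 and 20.0 TPM to 2.00 and 2.98 TPM, LOC_Os01g37000, a carboxyl-terminal peptidase, changed by -2.49 ± 0.26, and the retrotransposon protein gene LOC_Os04g35739 by -2.50 ± 0.20. The B12D call ended with a pseudocount of 0.1 (limma adjusted p = 0.0936). The cytosolic glutamine synthetase gene GLN1-2 (LOC_Os03g12290), which assimilates ammonium, changed by -1.47 ± 0.14 (limma adjusted p = 0.015).

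Of 44 lists, 13 passed camera in OE1, and none passed with an estimated correlation. The 82 carbon fixation genes had a median of -0.21, with none called and 1 lower when adjusted over the list alone (camera adjusted p = 0.000108, and adjusted p = 0.842 with an estimated correlation). The 33 flavonoid pathway genes had a median of -0.32 and the 17 TIFY/JAZ genes -0.34 (camera adjusted p = 0.000147 and 0.00154, and adjusted p = 0.292 and 0.307 with an estimated correlation), with 0 and 2 members lower when adjusted over the list alone and none called. The 116 pathogenesis-related genes had a median of 0.20, with 2 higher and 114 not called, and 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00555, and adjusted p = 0.842 with an estimated correlation). Their called members were LOC_Os07g03600 (1.84 ± 0.22) and LOC_Os12g36860 (1.39 ± 0.18), and both calls ended when TPM were rescaled by TMM factors (limma adjusted p = 0.058 and 0.0678) or by median-of-ratios factors (0.0516 and 0.0624). Of 78 WRKY genes 1 fell and 77 were not called, with 3 lower when adjusted over the list alone, and the median was -0.10 (camera adjusted p = 0.00853, and adjusted p = 0.842 with an estimated correlation). The one that fell, LOC_Os05g25770 annotated as WRKY45, went from 43.1 and 48.1 TPM to 20.1 and 21.8 TPM (limma adjusted p = 0.0409). Its call ended with both rescalings (limma adjusted p = 0.0711 and 0.0624).

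The 206 phenylpropanoid pathway genes had a median of -0.12, with 2 higher, 1 lower and 203 not called, and 6 higher and 5 lower when adjusted over the list alone. The 117 peroxidase genes had a median of -0.05, with 1 higher, the peroxidase gene LOC_Os02g14430, and with 2 higher and 3 lower when adjusted over the list alone. The 32 laccase genes had a median of -0.15, with none called and 1 lower when adjusted over the list alone, and the 26 genes for HSP70 and HSP90 chaperones a median of -0.18, with none called on either adjustment. The 26 nitrogen metabolism genes had a median of -0.16, with GLN1-2 called lower and 2 lower when adjusted over the list alone. The 9 root markers had a median of -0.41, with none called and 1 lower when adjusted over the list alone. The 29 shoot markers and the 26 light-harvesting genes had medians of -0.20 and -0.14, with none called on either adjustment. These 8 lists passed camera (adjusted p from 0.00853 to 0.0479), and each had adjusted p = 0.842 with an estimated correlation. The peroxidase call ended without treated ZH11 replicate 2, which takes no part in the fold and left the median as it was (camera adjusted p = 0.0968), and with TMM and median-of-ratios rescaling (0.0626 and 0.059) and a pseudocount of 0.1 (0.0528), as did the light-harvesting call with both rescalings (0.117 and 0.102).

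In OE1, 32 genes were higher and 29 lower after treatment, with 2387 genes at an unadjusted p under 0.05. With the spread taken from the 4 OE1 libraries alone the counts were 389 and 168. Without any of the 4 OE1 libraries, limma called none in either direction. At an unadjusted p under 0.05 there were then 644 higher and 432 lower genes without untreated replicate 1, 714 and 462 without untreated replicate 2, 797 and 682 without treated replicate 1, and 693 and 484 without treated replicate 2. Without treated ZH11 replicate 1 or 2 the counts were 210 and 207 higher and 131 and 131 lower, with the read-length term they were 245 and 94, and without untreated ZH11 replicate 1 or 2 they were 19 and 20 higher and 7 and 7 lower.

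The folds of the 2 genotypes share no library, but their calls share the variance estimated over all 8, so that Fisher's exact test of the overlap, which was run and takes the calls as independent, is not relied on here. Of the 44 genes that rose in ZH11 and the 32 that rose in OE1, 9 were the same. They included the P450 genes LOC_Os03g55240, LOC_Os07g23570 and LOC_Os06g03930 and the UDP-glycosyltransferase gene LOC_Os01g08440. Of 29 lower genes in each, 3 were shared, among them the B12D gene LOC_Os07g41340. Across 17423 genes with a mean of at least 5 TPM, which are not independent replicates, the log2 folds of both genotypes had a correlation of 0.211, and of 0.301 after the length gradient was removed. The shared counts also rested on single libraries. Without untreated ZH11 replicate 1 or 2 they were 4 and 0 higher and 0 and 0 lower, without any OE1 library 0 and 0, without treated ZH11 replicate 1 they were 35 and 36, and without treated ZH11 replicate 2 they were 30 and 16.

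**Figure D3:**
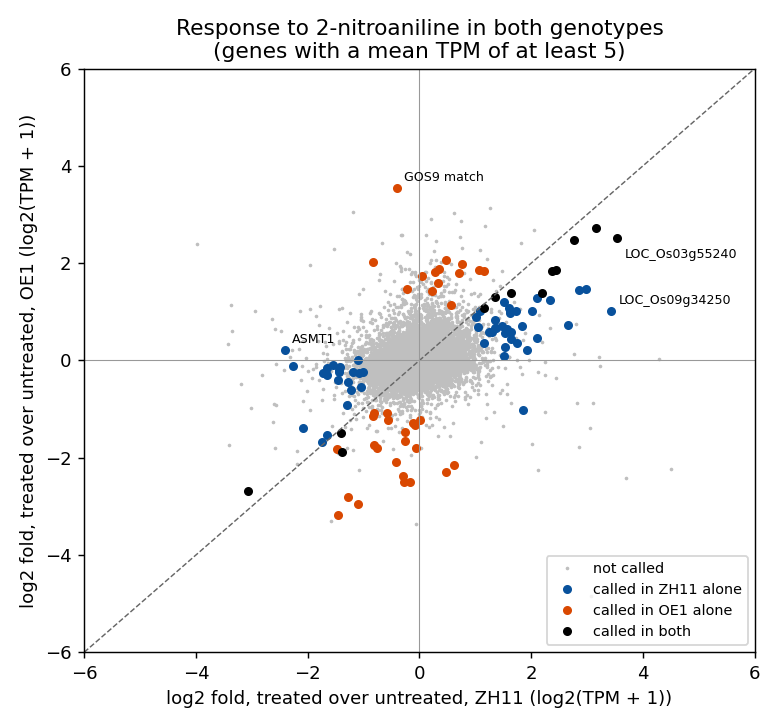
Log2 fold of treated over untreated plants on the log2(TPM + 1) scale in ZH11 (x axis) and OE1 (y axis), with 1 point per gene for 17423 genes with a mean of at least 5 TPM; color marks genes called in ZH11, in OE1 or in both, and the dashed line marks equal folds. The P450 gene LOC_Os03g55240 lies at 3.54 in ZH11 and 2.52 in OE1, and the UDP-glycosyltransferase gene LOC_Os09g34250 at 3.43 and 1.01.

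The third comparison asked how untreated OE1 differed from untreated ZH11. Many of the largest differences were at genes near 0 TPM in ZH11. LOC_Os02g52730, annotated as a ferredoxin-nitrite reductase, had 0.32 and 0.14 TPM in ZH11 and 44.1 and 41.5 TPM in OE1 (log2 fold 5.16 ± 0.25 SE, n = 2 per group, limma adjusted p = 0.000433). LOC_Os02g53240, of no described function, was higher in OE1 by 5.18 ± 0.25. Genes annotated as transposons among the largest differences were the AC transposase matches LOC_Os06g45810 (5.01 ± 0.25) and LOC_Os10g11330 (4.46 ± 0.25) and the retrotransposon gene LOC_Os07g32710. The last was not near 0 in ZH11, with 15.4 and 5.73 TPM there and 306 and 271 TPM in OE1 (4.78 ± 0.40, limma adjusted p = 0.0032). LOC_Os03g02470 was listed at 0 in both untreated ZH11 libraries and at 29.4 and 29.3 TPM in untreated OE1. LOC_Os11g35300, a match to cis-zeatin O-glucosyltransferase, and LOC_Os12g32390 were higher by 4.19 ± 0.31 and 4.12 ± 0.24. The matrix has no gene named for ScOYE3, so the transgene itself was not checked.

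Fewer genes were lower in OE1. LOC_Os01g42160, annotated as the maternally expressed gene family member MEGL14, had 12.7 and 12.2 TPM in untreated ZH11 and was listed at 0 in both untreated OE1 libraries. The adenylate kinase match MSTRG.5948 differed by -2.85 ± 0.35, the transaminase gene LOC_Os04g52440 by -2.33 ± 0.31, the methyltransferase match LOC_Os06g13390 by -2.06 ± 0.22 and ASMT1 (LOC_Os09g17560) by -1.58 ± 0.14. The calcium-dependent kinase match CPK7 (LOC_Os12g21784) differed by -1.80 ± 0.25 and the jacalin-like lectin gene LOC_Os12g14440 by -1.59 ± 0.23. Both called terpene synthase genes, LOC_Os04g27670 and LOC_Os08g04500, were lower, the first by -2.10 ± 0.20 (limma adjusted p = 0.00602) and the second with 6.30 and 6.61 TPM in ZH11 against 1.98 and 1.85 TPM in OE1 (limma adjusted p = 0.0484). With a pseudocount of 0.1 the calls of LOC_Os04g52440, LOC_Os06g13390 and LOC_Os08g04500 ended (limma adjusted p = 0.255, 0.102 and 0.0894).

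**Figure D4:**
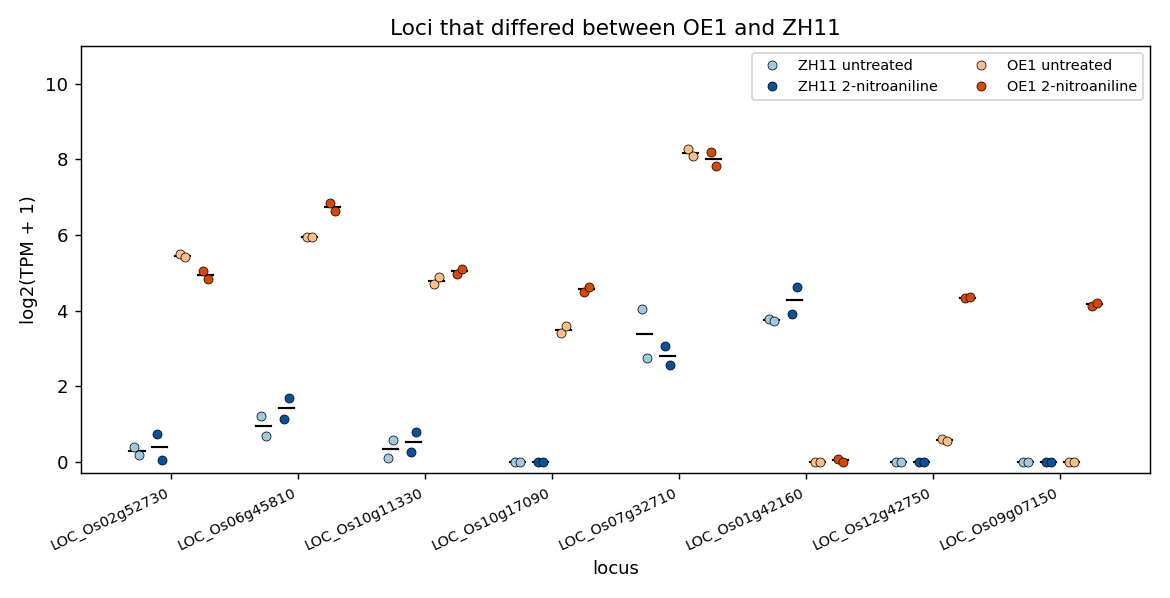
Level of 8 loci on the log2(TPM + 1) scale (y axis; x axis, locus), with 1 point per library, a bar at the mean of each group of 2 libraries, and color for the group. LOC_Os02g52730 had 0.32 and 0.14 TPM in untreated ZH11 and 44.1 and 41.5 TPM in untreated OE1, LOC_Os01g42160 is the reverse case, and LOC_Os09g07150 was above 0 in treated OE1 alone.

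By camera 6 lists differed between the untreated genotypes, none with an estimated correlation. All 9 root markers were above 0, with a median of 0.48, none of them called on either adjustment (camera adjusted p = 5.95e-07, and adjusted p = 0.529 with an estimated correlation). They deviated from the mean of all libraries by -0.16 and -0.25 in the untreated ZH11 libraries and by 0.15 and 0.32 in the untreated OE1 libraries. The 71 genes for late embryogenesis abundant proteins and dehydrins, which accumulate in drying tissue, had a median of 0.21, with 1 higher and 70 not called, and 4 higher when adjusted over the list alone (camera adjusted p = 3.05e-05, and adjusted p = 0.529 with an estimated correlation). The 28 small heat shock protein genes had a median of 0.18, with 1 higher, HSP16.9A (LOC_Os01g04370, 1.83 ± 0.27), and 2 higher when adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.529 with an estimated correlation). The list's call ended when the length gradient was removed (median 0.12, camera adjusted p = 0.0913), and the call of HSP16.9A ended with TMM and median-of-ratios rescaling (limma adjusted p = 0.0752 and 0.0674) and with a pseudocount of 0.1 (0.0528). The 76 BAHD acyltransferase genes had a median of 0.12 with 1 higher on either adjustment, LOC_Os01g15740 (3.03 ± 0.27), and the 50 quinone and zinc-binding reductase genes a median of 0.13 with none called on either adjustment (camera adjusted p = 0.0232 and 0.0394, and adjusted p = 0.709 and 0.917 with an estimated correlation). The reductase call ended with TMM and median-of-ratios rescaling (camera adjusted p = 0.066 and 0.058) and with a pseudocount of 0.1 (0.0523). The 18 terpene synthase genes had a median of -0.25, with 2 lower and 16 not called, the same number when adjusted over the list alone (camera adjusted p = 1.07e-05, and adjusted p = 0.641 with an estimated correlation).

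In untreated plants 100 genes were higher and 12 lower in OE1, with 1248 genes at an unadjusted p under 0.05. Without untreated ZH11 replicate 1 or 2 the counts were 44 and 40 higher and 6 and 1 lower, without untreated OE1 replicate 1 or 2 they were 36 and 37 higher and 1 and 1 lower, and without treated OE1 replicate 1 or 2, which take no part in the fold, 65 and 66 higher and 5 and 5 lower. Without treated ZH11 replicate 1 or 2 they were 141 and 142 higher and 28 and 26 lower.

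The fourth comparison asked how treated OE1 differed from treated ZH11. The same loci led. LOC_Os02g53240 was listed at 0 in both treated ZH11 libraries and at 41.8 and 55.4 TPM in treated OE1, and LOC_Os10g17090, an AC transposase match, at 0 in all 4 ZH11 libraries and at 21.5 and 23.8 TPM in treated OE1. LOC_Os06g45810, LOC_Os07g32710, LOC_Os12g39670, LOC_Os02g52730, LOC_Os10g11330 and LOC_Os11g35300 were higher by 5.33 ± 0.25, 5.20 ± 0.40, 4.59 ± 0.23, 4.55 ± 0.25, 4.52 ± 0.25 and 4.35 ± 0.31 (n = 2 per group, limma adjusted p from 0.000252 to 0.00161). Of 100 genes higher in untreated OE1 and 202 in treated OE1, 83 were the same. These comparisons share no library, but their calls share the variance estimated over all 8.

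Genes that had risen in treated ZH11, and others that had not, were lower in treated OE1. The UDP-glycosyltransferase gene LOC_Os09g34250 had 57.8 and 56.6 TPM in treated ZH11 and 15.8 and 14 TPM in treated OE1 (-1.87 ± 0.15, limma adjusted p = 0.00224). The P450 gene LOC_Os07g44110, which had also risen in ZH11, differed by -1.82 ± 0.22. The alpha carbonic anhydrase match LOC_Os08g32840 differed by -1.88 ± 0.22 and the peptidase gene LOC_Os01g37000 by -1.94 ± 0.26, and neither was called under treatment in ZH11. The 1-Cys peroxiredoxin B gene LOC_Os07g44440 differed by -1.32 ± 0.20 (limma adjusted p = 0.0387), and with the length gradient removed its difference was larger and no longer passed (limma adjusted p = 0.0712). LOC_Os02g54290, matched to the chromatin protein TONSOKU, differed by -2.39 ± 0.26, CPK7 (LOC_Os12g21784) by -1.90 ± 0.25 and the beta-glucosidase gene BGLU34 (LOC_Os10g17650) by -1.41 ± 0.19, and the call of LOC_Os02g54290 ended with a pseudocount of 0.1 (limma adjusted p = 0.0533). MEGL14 (LOC_Os01g42160) had 14.2 and 23.7 TPM in treated ZH11 and was listed at 0.06 and 0 TPM in treated OE1. The retrotransposon gene LOC_Os01g21135 differed by -1.70 ± 0.24, a call that ended without treated ZH11 replicate 2 at -1.63 (limma adjusted p = 0.0575).

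Of 56 histone genes tested, 9 were higher in treated OE1 than in treated ZH11 and 47 were not called, with 13 higher when adjusted over the list alone, and the median was 0.57 (camera adjusted p = 3.22e-12, and adjusted p = 0.325 with an estimated correlation). The histone H3 gene LOC_Os01g64640 was higher by 1.43 ± 0.17 and the histone H2A gene LOC_Os12g34510 by 1.30 ± 0.21. With the length gradient removed neither passed, at 1.05 (limma adjusted p = 0.0679) and at 0.93, under the fold required, and the list's median was 0.17 (camera adjusted p = 0.00592, and adjusted p = 0.867 with an estimated correlation). The call of LOC_Os12g34510 also ended with TMM and median-of-ratios rescaling (limma adjusted p = 0.0676 and 0.0642) and with a pseudocount of 0.1 (0.0559). The 40 expansin genes had a median of 0.27 with none called and 2 higher when adjusted over the list alone, and the 329 ribosome genes a median of 0.30 with none called on either adjustment (camera adjusted p = 0.000188 and 5.85e-10, and adjusted p = 0.577 and 0.843 with an estimated correlation). The ribosome call ended with the length gradient removed (median 0.02, camera adjusted p = 0.571). The 71 genes for late embryogenesis abundant proteins had a median of 0.16 with 1 higher on either adjustment (camera adjusted p = 0.00228, and adjusted p = 0.66 with an estimated correlation), and this call ended with the length gradient removed (median 0.01, camera adjusted p = 0.571).

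A further 7 lists passed camera with all libraries and lost the call both without treated ZH11 replicate 2 and with the length gradient removed. Of the 116 pathogenesis-related genes 2 were higher, 3 when adjusted over the list alone, with a median of 0.27 (0.12 without that library), the called ones being the thaumatin genes LOC_Os06g47600 (1.84 ± 0.26) and LOC_Os12g43440 (1.62 ± 0.21). The call of LOC_Os06g47600 ended without that library at 1.65 (limma adjusted p = 0.0501). Of the 98 AP2/ERF transcription factor genes 1 was higher on either adjustment, LOC_Os02g13710, a match to a protein that binds dehydration-responsive elements (9.61 and 9.80 TPM against 3.22 and 2.28 TPM), and the median was 0.20 (0.10 without that library). The 110 ABC transporter genes had a median of -0.26 (0.00 without that library) with none called on either adjustment. The medians of the 26 light-harvesting, 50 quinone reductase, 28 small heat shock protein and 18 terpene synthase genes were 0.34, 0.14, 0.25 and -0.37, and 0.05, -0.01, 0.18 and -0.12 without that library. With the length gradient removed the medians of the pathogenesis-related, AP2/ERF, ABC transporter, light-harvesting, quinone reductase, small heat shock protein and terpene synthase genes were 0.04, 0.13, 0.03, 0.16, 0.15, -0.06 and -0.05, so that the median of the quinone reductases did not shrink although its call ended (camera adjusted p = 0.0987). Called members were 0, 1 higher and 1 lower, 0, and 0, and adjusted over the list alone 0, 1 higher and 1 lower, 1 higher, and 2 lower. The 7 lists had camera adjusted p from 0.00153 to 0.0353, and adjusted p = 0.843 with an estimated correlation except 0.577 for the small heat shock proteins.

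**Figure D5:**
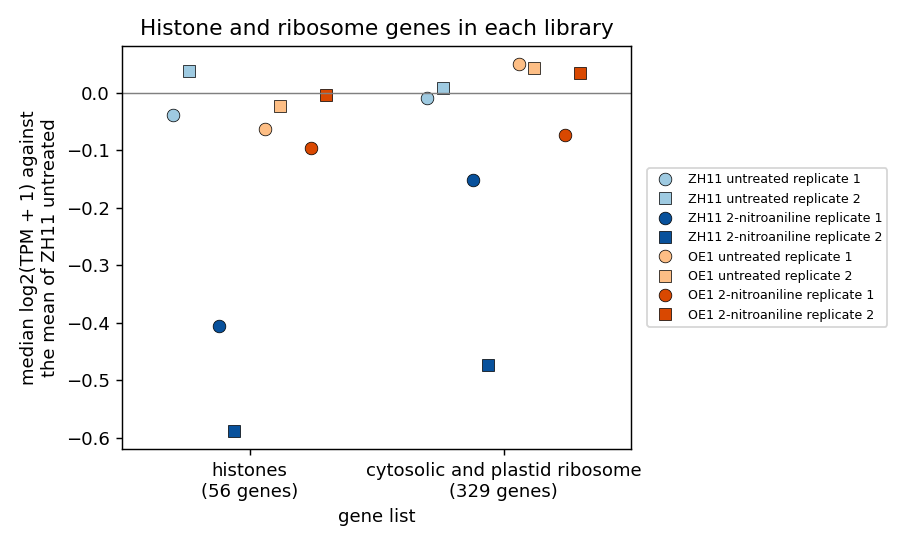
Median log2(TPM + 1) of 56 histone and 329 ribosome genes (x axis, gene list) in each library, set against the mean of the untreated ZH11 libraries (y axis); color marks the group, circles replicate 1 and squares replicate 2. Histone genes lay at -0.41 and -0.59 in treated ZH11 and between -0.10 and 0.04 in the other 6 libraries.

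Under treatment 202 genes were higher and 39 lower in OE1, with 3812 genes at an unadjusted p under 0.05. With the spread taken from the 4 treated libraries alone the counts were 42 and 2. Without treated OE1 replicate 1 or 2 the counts were 50 and 46 higher and 3 and 2 lower, and without treated ZH11 replicate 1 or 2 they were 2093 and 171 higher and 1761 and 44 lower. Without untreated OE1 replicate 1 or 2, which take no part in the fold, they were 70 and 70 higher and 5 and 5 lower, and without untreated ZH11 replicate 1 or 2 they were 160 and 160 higher and 17 and 17 lower.

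The fifth comparison tested whether the response to 2-nitroaniline differed between the genotypes. The UDP-glycosyltransferase gene LOC_Os09g34250 rose by 3.43 in ZH11 and had a log2 fold of 1.01 in OE1, a difference of -2.42 ± 0.22 (n = 2 per group, limma adjusted p = 0.0378). ASMT1 (LOC_Os09g17560) fell in ZH11 and stayed at 14.1 and 13.6 TPM before and 15.9 and 16.4 TPM after treatment in OE1, a difference of 2.61 ± 0.20 (limma adjusted p = 0.0187). The jacalin-like lectin gene LOC_Os12g14440 rose in OE1 and had 13 and 11.2 TPM before and 7.55 and 10.4 TPM after treatment in ZH11, a difference of 3.95 ± 0.32 (limma adjusted p = 0.0229). Other genes called were LOC_Os09g07150, LOC_Os12g42750, LOC_Os01g33720 and MSTRG.19809, all listed at 0 in the 4 ZH11 libraries and between 8.46 and 19.4 TPM in treated OE1. With a pseudocount of 0.1 no call remained (limma adjusted p = 0.0563 for LOC_Os09g34250, ASMT1 and LOC_Os12g14440, and 0.233 for LOC_Os09g07150 and LOC_Os12g42750), and with a block for the replicate number limma called 0 and 0, with 889 higher and 541 lower genes at an unadjusted p under 0.05. LOC_Os01g33720 and MSTRG.19809 fall outside the rule for named genes and were chosen after their values were seen.

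By camera 12 lists differed in their response, none with an estimated correlation. No histone gene was called by limma over all genes tested, 11 of 56 were higher in OE1 when adjusted over the list alone, and the median difference was 0.58 (camera adjusted p = 6.35e-16, and adjusted p = 0.202 with an estimated correlation). The 40 expansin genes had a median difference of 0.36 (camera adjusted p = 1.32e-05, and adjusted p = 0.552 with an estimated correlation) and the 9 root markers one of -0.50, with 3 lower when adjusted over the list alone (camera adjusted p = 3.01e-05, and adjusted p = 0.865 with an estimated correlation). The 91 NAC transcription factor genes had a median difference of -0.19 (camera adjusted p = 0.0421, and adjusted p = 0.897 with an estimated correlation). The 26 nitrogen metabolism genes had one of -0.23, with 2 lower when adjusted over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.897 with an estimated correlation), and this call ended with the length gradient removed (median -0.15, camera adjusted p = 0.133). For ribosome, ABC transporter, HSP70 and HSP90, light-harvesting, pathogenesis-related, shoot marker, and thioredoxin and glutaredoxin genes the medians were 0.23, -0.26, -0.27, 0.32, 0.27, 0.23 and 0.17. These 7 lists passed camera (adjusted p from 5.15e-08 to 0.0449, and adjusted p of 0.865 or 0.897 with an estimated correlation), and each lost the call without treated ZH11 replicate 2 (adjusted p from 0.0609 to 0.723) and with the length gradient removed (0.154 to 0.84). In the same order their medians were 0.10, -0.04, 0.07, 0.17, 0.13, 0.14 and 0.07 without that library, and 0.04, -0.02, -0.04, 0.18, 0.13, 0.17 and 0.04 with the gradient removed. Among members of the lists other than histones, root markers and nitrogen metabolism, 3 pathogenesis-related genes were higher when adjusted over the list alone and no other was called.

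For the response itself limma called 7 genes higher and 1 lower, and 1630 genes had an unadjusted p under 0.05. Without treated ZH11 replicate 1 it called 1336 and 1373, and without treated ZH11 replicate 2 it called 12 and 16. Without any other library it called none. The higher and lower genes at an unadjusted p under 0.05 then numbered 724 and 574 without untreated ZH11 replicate 1, 1171 and 467 without replicate 2, 501 and 320 without untreated OE1 replicate 1, 556 and 316 without replicate 2, 631 and 553 without treated OE1 replicate 1, and 524 and 311 without replicate 2.

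The rice relatives of the introduced enzyme are the OPR genes, which encode oxophytodienoate reductases, among them OPR7 of jasmonate synthesis. None of 10 OPR genes with a mean of at least 1 TPM passed limma in any of the 5 comparisons. OPR1 (LOC_Os06g11290) had 9.17 and 7.82 TPM in untreated ZH11 and 10.9 and 15.9 TPM in treated ZH11 (0.58 ± 0.25, limma adjusted p = 0.401). OPR5 (LOC_Os06g11210) had a log2 fold of 0.43 ± 0.18 in ZH11 and -0.39 ± 0.18 in OE1, with a difference of -0.81 ± 0.25 (limma adjusted p = 0.595). OPR7 (LOC_Os08g35740) had -0.21 ± 0.15 in ZH11 and -0.13 ± 0.15 in OE1, with 36.9 to 48.2 TPM over all libraries. Several OPR genes are near-identical copies, so the split of reads among them is uncertain.

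The authors' deposited tables list only genes the authors called, from a test whose name is not given in the sources used here. The authors' deposited table for ZH11 has 81 higher and 34 lower genes under treatment, of which 35 and 23 were also called here, and the authors' deposited table for OE1 has 364 and 167, of which 28 and 29 were. The authors' deposited tables for the genotypes have 132 higher and 43 lower genes in untreated OE1, of which 60 and 11 were also called here. For treated OE1, 192 higher and 62 lower genes of the authors' deposited table were tested here, and 105 and 23 were called. Every gene of the authors' deposited tables that was tested here had the same sign in both. That was nearly fixed in advance, since the same libraries were used and the smallest absolute log2 fold listed was 1.001.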

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

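Among the tests in this part, those of the library that stands apart, of the detoxification genes, of transposon release, of assembled gene models, of the wider window of loci, of the genes other than kinesins and of genes selected on replicate 1 libraries were chosen after the result was seen, and the removal of the length gradient was also added later. The tests of the histone and mitotic genes against matched random lists, of loci within 10 of each other and of genes selected on replicate 2 libraries were written before. The 8 genes in this paragraph were singled out because their treatment effect in OE1 differed from that in ZH11 by the limma test of the difference. On the log2 scale LOC_Os09g17560 (ASMT1) differed by 2.611, LOC_Os12g14440 (jacalin-like lectin) by 3.954 and LOC_Os09g34250 (UDP-glycosyltransferase) by -2.421. LOC_Os12g42750 differed by 3.768, and 1 further locus, not described here, by 3.222. LOC_Os09g07150, LOC_Os01g33720 and MSTRG.19809, listed at 0 in the 6 other libraries, differed by 4.164, 3.245 and 3.756, which for genes at 0 only restates their level in treated OE1.

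The histone list passed camera for the difference of the treatment effects, with a median of 0.579 and none of its 56 genes called (camera adjusted p = 6.35e-16, and adjusted p = 0.202 with an estimated correlation). The 10000 random lists matched on length and TPM had a median of 0.199 and reached 0.327 at the upper end of their central interval. Removing the gradient left 0.266 (camera adjusted p = 1.9e-05, and adjusted p = 0.52 with an estimated correlation). The random lists hold unrelated genes and were not matched on GC content, so their interval may be too narrow for genes that vary together. The length gradient thus covered part of the difference, and whether the rest exceeds the spread between libraries is undecided. The tables argue against the library that stands apart as the whole cause, since 0.38 remained without it. Fewer dividing cells in treated ZH11 stays open. The 74 mitotic genes had a median of -0.046 against -0.041 at the upper end for random lists, a margin judged too small only after it was seen. Of them 56 are kinesins, matched by text in their annotation. Not all of these need act in cell division, so the median of the list cannot decide. Of the 18 others 16 were above 0 (median 0.26). The 60 DNA replication genes had a median difference of -0.002 (camera adjusted p = 0.763), and of 0.135 without treated ZH11 replicate 2 (camera adjusted p = 0.0227, and adjusted p = 0.868 with an estimated correlation), and the root and shoot markers also moved (-0.497 and 0.227), so that a change in tissue share stays open, untested.

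Of 17 detoxification genes from 8 lists that rose over both genotypes, 15 rose less in OE1, with medians of 2.34 in ZH11 and 1.21 in OE1 and a median difference of -0.647, but only 1 was called by itself, and the whole P450, UDP-glycosyltransferase, aldo-keto reductase and glutathione S-transferase lists did not pass camera (medians -0.099, 0.031, 0.135 and -0.131, adjusted p = 0.176, 0.864, 0.102 and 0.104), the last passing without treated ZH11 replicate 2 or with the length gradient removed (camera adjusted p = 5e-06 and 6.7e-05, and adjusted p = 0.541 and 0.52 with an estimated correlation). For these same genes the difference was -0.629 without the library that stands apart and -0.621 with the length gradient removed. The genes were selected with that library included and not selected anew, so leaving it out afterwards cannot decide its part. The second value argues against the length gradient as the whole cause, for these genes only. A smaller response of responsive genes in general was not decided by the median of -0.088 over all of them, which pooled -0.48 for 65 higher genes and 0.253 for 36 lower genes. The 65 include the 17 detoxification genes. The 48 others had a median of -0.079, so that a smaller rise was not seen over the other risers as a set. Genes selected on the libraries of 1 replicate number and measured on those of the other ran the opposite way (0.309 and 0.124). They were selected by effect size alone, on 1 library per group, with higher and lower genes together. Those selected on replicate 2, which holds the library that stands apart, had 0.365 in ZH11 and 0.736 in OE1 on replicate 1. Hence they decide nothing about the genes that rose. Of the 48 other risers 27 rose less in OE1 (median -0.079, Fisher's exact test p = 0.02, with genes that are not independent). The root markers moved the same way (median difference -0.497, 0 of 9 above 0), and neither a change in the share of root tissue nor lower exposure of OE1 to the compound, which could give the same pattern, was tested.

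In OE1, 83 genes were higher in both conditions, and 57 of them had a mean of at most 0.5 TPM in both ZH11 groups. Of the LOC_Os loci 3.8% had another within 10 loci, against a median of 0 and an upper end of 7.7% for random sets. Under the bound written before, a share under the upper end counted against blocks of another parental genome. The window of 50 loci, added after that result was seen, gave 23.1%, against a median of 9.6% and an upper end of 23.1%. Blocks are left open here, which departs from that bound. The tables argue against assembled gene models as the whole cause, since 52 LOC_Os loci were higher and 5 lower. Yet 31 of the 83 were MSTRG genes, against 1327 among all genes tested (odds ratio 11, Fisher's exact test p = 6.31e-19). Assembled gene models therefore stay open as part of the cause. Transposon descriptions were held by 14 of the 83 (16.9% against 3.7% of all genes tested, odds ratio 5.41, Fisher's exact test p = 1.74e-06), a test chosen from the same data. Its background was all genes tested, not genes near 0 in ZH11, so it cannot decide on release of silent transposons. The descriptions were matched by text, which also takes in genes such as LOC_Os10g36980, whose protein match is a cytochrome P450. Genes without a description, such as MSTRG.19809, could not be matched, so the 14 do not bound how many of the 83 release could cover. Release stays open, as do reads from paralogs, strain variants and changes from tissue culture or the transgene, since sequence data were not used.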

How the results depend on the processing

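Removal of the length gradient, the read-length term, the shorter-read libraries alone and the weights by spread were chosen after the data were seen, and all other settings before the data were examined, but the fit without the mean-variance trend was applied to single genes only later. For comparisons of 2 groups the rule for named genes took only genes whose groups did not overlap, which fixes the sign under most settings. Hence it tells little that none of 88 named calls changed sign under any setting. Of these, 81 passed with TMM factors and 81 with median-of-ratios factors, 72 and 76 with pseudocounts of 0.1 and 5, 57 without the filter, 84 with the length gradient removed, 59 with the replicate block, 83 with the read-length term, 86 with only the shorter-read libraries, 59 with the weights by spread, 84 without the mean-variance trend, and 26 to 88 when a library was left out. Of 49 list calls, 46 passed under each rescaling, 47 with a pseudocount of 0.1, 33 without treated ZH11 replicate 2, 31 with the length gradient removed and 0 with an estimated correlation. Among named calls that these settings could test, 45 passed and 37 did not with only the 4 libraries of the 2 groups. With a mean TPM of at least 5, 65 passed and 5 did not. Rescaling moved the all-gene median to at most 0.038 in absolute size. Counts below are higher then lower, and where not stated otherwise the cause was not tested.

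Leaving out each library in turn, with a lone sample assumed to vary like the other groups, gave 0 to 1282 and 0 to 1353 for treatment in ZH11, 0 to 210 and 0 to 131 for treatment in OE1, 36 to 142 and 1 to 28 for untreated genotypes, 46 to 2093 and 2 to 1761 for treated genotypes, 0 to 1336 and 0 to 1373 for the difference of the effects, and 0 to 35 and 0 to 36 for shared treatment calls. For treatment in ZH11, treated genotypes and the difference, the highest counts came without treated ZH11 replicate 1, where the library that stands apart alone represents its group and adds no spread. Lists past camera without treated ZH11 replicate 2 were 17 for treatment in ZH11 and 7 for treated genotypes.

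Without the filter, which adds genes to the adjustment, the counts were 13 and 14 for treatment in ZH11, 19 and 17 in OE1, 126 and 19 for treated genotypes, 5 lower for the difference of the effects, and 4 and 0 shared. With a mean TPM of at least 5, which removes genes, they were 37 and 6 for untreated genotypes, 78 and 21 for treated genotypes, and 2 higher for the difference. With a pseudocount of 5 they were 57 higher for treatment in OE1, 61 and 6 for untreated genotypes, and 6 lower shared. With a pseudocount of 0.1 the difference gave 0 and 0, with 904 and 648 at a limma unadjusted p under 0.05. The difference had 2 lower with median-of-ratios factors and 2 with TMM factors, which also gave 11 lists for treatment in ZH11. Without the mean-variance trend 5 lower genes were shared.

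With only the 4 libraries of the 2 groups, treatment in ZH11 gave 0 and 0, with 551 and 693 at a limma unadjusted p under 0.05, treatment in OE1 389 and 168, and treated genotypes 42 and 2. That setting changes both the pooled spread and the degrees of freedom, and which of them moved the counts was not tested. With the replicate block the counts were 14 and 7 in ZH11, 13 and 12 in OE1, 111 and 19 for treated genotypes, 0 and 0 for the difference, with 889 and 541 at a limma unadjusted p under 0.05, and 3 and 1 shared. The correlations of library deviations between groups ran from -0.28 to 0.233, the highest between the ZH11 groups, where the replicate number coincides with read length, so that no pairing over all groups was seen. With weights by spread they were 7 and 1 in ZH11, 395 and 180 in OE1, 181 and 40 for untreated genotypes, 49 and 8 for treated genotypes, 1 and 0 for the difference, with 543 lower at a limma unadjusted p under 0.05, and 0 lower shared.

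With the length gradient removed they were 96 and 69 in ZH11, 102 and 79 in OE1, 63 lower for treated genotypes, 4 lower for the difference, and 25 and 12 shared, with 6 lists for treated genotypes and 6 for the difference. With the read-length term they were 117 and 88 in ZH11, 245 and 94 in OE1, and 33 and 20 shared. With only the shorter-read libraries, which leaves 1 library per ZH11 group, assumed to vary like the OE1 groups, they were 90 and 81 in ZH11, 383 and 166 in OE1, 19 lower for untreated genotypes, 395 and 80 for treated genotypes, 115 and 33 for the difference, and 28 and 15 shared. With an estimated correlation 0 lists passed camera in each of the 5 comparisons (0, 0, 0, 0 and 0), with 5, 2, 3, 3 and 2 at an unadjusted p under 0.05. The median of the ABC transporters between treated genotypes went from -0.257 to 0.025 with the length gradient removed, and the median difference of HSP70 and HSP90 genes from -0.266 to 0.068 without treated ZH11 replicate 2.

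Tests on counts with edgeR or DESeq2 were not run, since estimated counts were deposited only for genes the authors called. Reads per library ran from 42.1 M to 51.6 M in ZH11 and from 50.7 M to 56.5 M in OE1, so that depth went partly with genotype. The lowest depth was that of treated ZH11 replicate 2. What depth limits was not tested.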

Other observations

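In this part the test of the genotype split, the counts by class of cell division genes, the mitotic genes without treated ZH11 replicate 2, the random lists for ribosome genes and the genes selected on replicate 1 libraries were chosen after the result was seen. The removal of the length gradient was devised after the data were seen, but for the response of all treatment-responsive genes its bounds were written before that result. Among genes of cell division not described above none was called. For the difference of the treatment effects the proliferating cell nuclear antigen gene LOC_Os02g56130, a sliding clamp of DNA replication, had 0.58, and the cyclin-dependent kinase genes CDKB1-1 (LOC_Os01g67160) and CDKB2-1 (LOC_Os05g40540 and LOC_Os08g40170) had 0.28, 0.25 and 0.67. Of 10 B-type cyclin genes 8 were above 0 (median 0.244), with 0.36 for LOC_Os01g59120 and -2.35 for LOC_Os02g55720, as were all 4 ribonucleotide reductase genes (median 0.157), while 39 of 56 kinesin genes were below 0 (median -0.13). Without treated ZH11 replicate 2 the 74 mitotic genes, 56 of them kinesins matched by text, had a median difference of 0.179. The upper end of the central interval of matched random lists was 0.109. The 329 ribosome genes had 0.23, at the upper end for their random lists. Glutathione S-transferase genes did not pass with all libraries, and had a median difference of -0.17 without treated ZH11 replicate 2 (camera adjusted p = 5e-06) and -0.24 with the length gradient removed (6.7e-05), and adjusted p = 0.541 and 0.52 with an estimated correlation.

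A hypothesis that all treatment-responsive genes change less in OE1 was not borne out as one pattern. Over 101 responsive genes, 65 higher and 36 lower, the median effect along the direction of the response was 1.371 in ZH11 and 1.369 in OE1, with a median difference of -0.088 and 57 genes changing less in OE1. That median cancels 2 opposite ones, -0.48 for the 65 higher genes and 0.253 for the 36 lower genes. The 65 include the 17 detoxification genes, and the 48 others had -0.079. The 3 tests of the hypothesis were kept, although the rule that left them undecided was set after the median of -0.088 was seen. On replicate 1 libraries, with genes selected on replicate 2 libraries, OE1 minus ZH11 was 0.309 (effects of 0.365 in ZH11 and 0.736 in OE1), and with the roles exchanged 0.124. That selection used effect size, a shared sign and the level of the gene on 1 library per group, without a test, so it decides nothing. With the length gradient removed the median difference over the 101 genes was -0.065. The untreated level of OE1 minus that of ZH11 along the direction of the response was -0.099.

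Loci off in 1 group of OE1 (at most 0.1 TPM) and on in the other (at least 5 TPM) numbered 7, and between the ZH11 groups 4. Whether treated and untreated OE1 plants differed in genome could not be decided from the 7, and the name of this pattern was reworded after the run with test and bounds unchanged. Over the 35 ways of splitting the libraries 4 against 4, treated against untreated gave 64 genes, and 2 splits gave as many, the other being the genotype split with 166. Hence this test decided nothing about chance in the form in which it was written, since the higher split is another true grouping. The genotype split gave 166 against 64 for the highest other, so that 1 of 35 splits gave as many, and all splits other than these gave at most 2.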
